A study of Homo sapiens with 7 samples.

How the data were processed

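Expression was measured on 7 arrays, 4 of cultured human corpus cavernosum smooth muscle cells transfected with an siRNA against the MaxiK potassium channel and 3 of untreated cells. Per the labels' protocols, the cells were explant cultures, the siRNA was used at 30 nM with a lipid transfection reagent, and RNA was taken 48 h later. Per the labels, biotin-labelled target from total RNA was hybridised to Affymetrix arrays. The labels call the control cells untreated, and no array of cells given a non-targeting siRNA or the reagent alone was used here. Groups and replicate numbers came from the sample titles. The labels do not say that replicates were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

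The deposited table held log2 values per probe set. The log2 scale was read from the deposited values, whose array medians lay between 4.40 and 4.61, and near-equal quantiles on all arrays but siRNA replicate 2 show that a common scale had been set. The summary method, background correction and software were not given in the sources used here. Where arrays are put on a common scale, a change shared by most genes would not be seen. The number of arrays limits the precision. No further normalization was applied.

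The array held 54675 probe sets, and the platform's annotation paired 41097 with 1 gene symbol and 1801 with several, which were not used. A further 11777 were unnamed here. Removing 59 probe sets of genes that are never reported left 41038, of which 40984 were matched by Entrez identifier and 0 had a symbol updated. For each of 19740 genes the probe set with the highest mean over the 7 arrays was kept. Genes at or above the 40th percentile of mean level, a log2 value of 4.60, were tested, which left 11844.

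Group differences were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Single values and list means were also compared by an exact permutation test over the 35 splits of the 7 arrays into 4 and 3, two-sided, whose smallest p is 0.0286. The 37 gene lists were written before the data were examined, and 35 had at least 3 tested members. They were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with a correlation estimated per list and with fry. Counts "adjusted over the list alone" used Benjamini-Hochberg within 1 list. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

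The test, the filter, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took KCNMA1 with every probe set, then the 14 genes with the largest changes each way past the threshold with all arrays apart, then up to 4 tested members of each list with the smallest adjusted p, and any member of the MaxiK subunit and opiorphin lists. The genes named from other lists are a selection of those the rule allowed. The alternatives were quantile normalization, median centring, no filter and a filter at the 60th percentile, other ways to combine probe sets, moderated variances with a trend, array weights, the replicate number as a block, and leaving out each array. Fits with a block for sample sets seen in the data were added after the data were examined. That block was drawn from the values tested, so p-values and counts from these fits may overstate the evidence.

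The pairing of replicate numbers was checked from the correlation, across genes, of deviations from the group means. It was 0.277, 0.12 and 0.348 for numbers 1, 2 and 3, each above the limit of 0.1 set for treating the numbers as pairs, so the blocked value is given where it changes a call. The labels do not state what a number marks. No untreated sample shares the number of siRNA replicate 4, so the fit with the block used the other 6 arrays. The check was weak for number 2, at 0.0852 when siRNA replicate 4 was left out of the means, and siRNA replicate 1 was at 0.304 with untreated replicate 2 while siRNA replicate 4 was at 0.348 with untreated replicate 3.

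The gene test was tested on simulated data with 200 changed genes among 11844. For all 7 arrays, with random noise of the measured size on siRNA replicate 2, it recovered 11.7% of log2 changes of 1 and 47.2% of log2 changes of 2. That noise had no trend with expression level, unlike the measured deviation of the sample, so these rates may not hold for it. For the 6 arrays without siRNA replicate 2 it recovered 56.6% and 87.7%, and 5.31% of its calls were false. The list test found a simulated shift of 0.5 in 20 of 20 draws and called 1 of 640 unshifted lists. The simulated genes were independent, whereas the list test allows for a small preset correlation and measured genes may share larger shifts. These list rates may therefore not hold for the measured lists.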

Results

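Gene expression was measured on 7 Affymetrix arrays of cultured smooth muscle cells from the human corpus cavernosum, the erectile tissue. In 4 samples the MaxiK channel, a large-conductance calcium- and voltage-activated potassium channel, had been silenced for 48 h with 30 nM siRNA, and 3 samples were untreated. The comparison asks how silencing the channel altered expression across the genome. Values are log2 expression as deposited, and differences are siRNA minus untreated. Of the arrays, 6 correlated at 0.978 to 0.996 with one another across probe sets, while siRNA replicate 2 reached only 0.878 to 0.886 with any other. The SD of its values was 2.05, against 2.46 to 2.52 on the other arrays, and its GAPDH 3' control probe set read 9.73 against a mean of 12.92 in untreated samples. The median difference over all tested genes was -0.159, and -0.0196 without siRNA replicate 2. Relative to that median the interferon-stimulated list differed by 1.51 and the mitosis list by -0.97.

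KCNMA1, which encodes the pore-forming subunit of MaxiK, was lower in 4 of 4 siRNA samples than in any untreated sample. Its brightest probe set, 221584_s_at, measured 6.31 ± 0.90 (SD, n = 4) in siRNA samples and 8.75 ± 0.26 (SD, n = 3) in untreated samples, a difference of -2.44 or 5.41-fold (exact permutation p = 0.0286, the smallest possible). A further probe set, 221583_s_at, differed by -2.92, or 7.59-fold, with the same exact p of 0.0286. The dim probe sets 228414_at and 214921_at differed by -0.39 and 0.15, and their exact p-values were 0.40 and 0.371. Exact tests of single values ignored the pairing by replicate number. Splits that part all 3 same-numbered pairs are too few for a p under 0.05. In the fit over all genes, the adjusted p of KCNMA1 was 0.751 with limma. Against the untreated mean, 221584_s_at was 10.6-fold lower in siRNA replicate 1, 3.19-fold in replicate 2, 7.99-fold in replicate 3 and 3.17-fold in replicate 4. In siRNA replicate 2, however, bright genes read lower in general. Its differences on 221584_s_at and 221583_s_at stood at percentiles 33.1 and 7.31 of probe sets of the same level. The falls in that sample are therefore not by themselves evidence of silencing. Accessory subunits were dim: KCNMB1 measured 2.68 and 2.27 in siRNA and untreated samples, KCNMB2 2.24 and 2.08, KCNMB4 3.85 and 3.74, LRRC38 3.09 and 2.39, LRRC52 2.04 and 2.23, and LRRC55 1.90 and 1.72, all under the filter. The dim LRRC38 was higher in 4 of 4 siRNA samples than in any untreated sample, by 0.69 (exact permutation p = 0.0286). KCNMB3 passed the filter and differed by 0.20 (limma adjusted p = 0.758), or by -0.00095 without siRNA replicate 2. The opiorphin genes OPRPN, SMR3A and SMR3B, whose family encodes secreted peptidase inhibitors, were under the filter too, with differences of 0.042, 0.35 and 0.22.

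**Figure D1:**
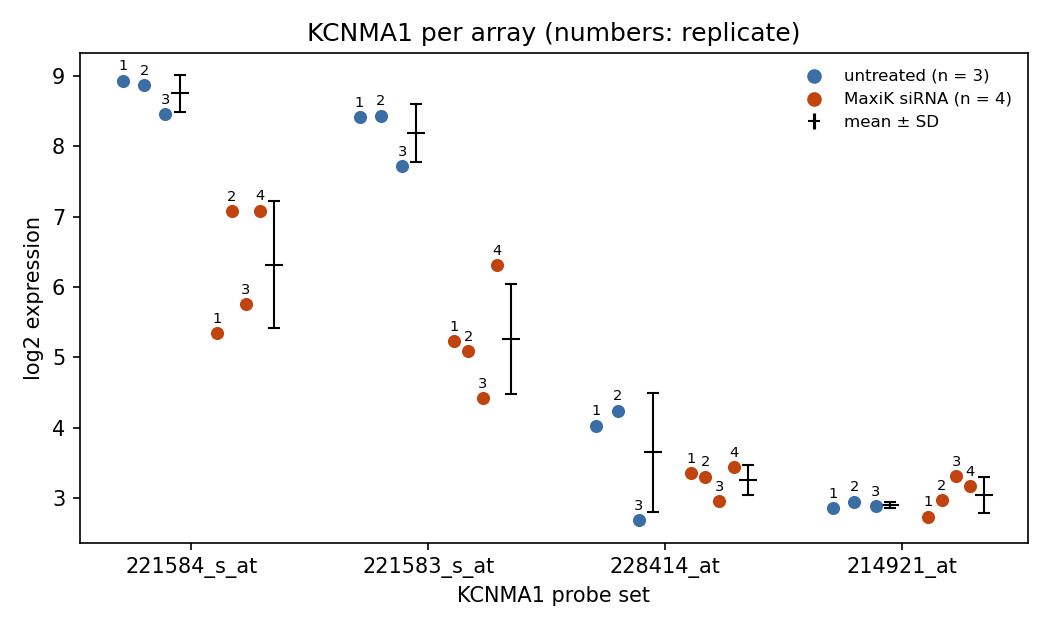
Log2 expression of the 4 KCNMA1 probe sets on each array, untreated (blue, n = 3) and MaxiK siRNA (red, n = 4), with replicate numbers and the mean ± SD in black. On 221584_s_at the siRNA samples sit between 5.34 and 7.08 and the untreated samples between 8.45 and 8.93; the pair of dim probe sets lies at 4.24 or lower.

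Interferon-stimulated genes, which encode antiviral proteins, were higher after siRNA treatment. HERC5, a ubiquitin-like ISG15 ligase, rose 6.90-fold (log2 2.79, SE 0.20, limma adjusted p = 0.0263) and was above every untreated value in 4 of 4 siRNA samples. Its untreated mean of 3.01 lay under the filter level of 4.60, so the size of the fold depends on background, and its mean over the 7 arrays cleared that level by 0.005. RSAD2, which encodes the antiviral enzyme viperin and had an untreated mean of 3.44, differed by 4.49 (SE 0.42, limma adjusted p = 0.0757), IFIT1 by 2.91 (SE 0.37, limma adjusted p = 0.282) and IFI44 by 2.16 (SE 0.27, limma adjusted p = 0.282). Of 50 tested members, 43 had positive and 7 negative differences, and 27 rose and 0 fell when adjusted over the list alone, against 1 over all genes. The list mean was 7.51 ± 0.48 (SD, n = 4) in siRNA and 6.15 ± 0.38 (SD, n = 3) in untreated samples, a difference of 1.35 (exact permutation p = 0.0286, the smallest possible, or 0.625 adjusted over the 35 lists). The list rose relative to other genes with camera (adjusted p = 4.98e-35), and adjusted p = 0.40 with an estimated correlation. Without siRNA replicate 2 the difference was 1.55 and 35 members rose adjusted over the list alone.

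HERC5 was the only gene of 11844 past the threshold, and limma gave 468 genes (165 higher, 303 lower) at an unadjusted p under 0.05, or 3.95% of those tested. That share lies under the 5% that such a cutoff gives by chance. All siRNA samples lay above all untreated samples for 448 genes and below for 677, together 9.50%, where chance gives 5.71%. With the replicate number as a block, which leaves out siRNA replicate 4, no gene passed: the count was 0, with 392 at an unadjusted p under 0.05, and HERC5 had an adjusted p of 0.66. Leaving out siRNA replicate 2 also gave 1 gene, HERC5 at an adjusted p of 0.000785, with 1387 at an unadjusted p under 0.05, whereas leaving out any other array gave 0 genes with limma and HERC5 at 0.128 to 0.451. The arrays also fell into sample sets: siRNA replicate 1 with untreated replicates 1 and 2, and siRNA replicates 3 and 4 with untreated replicate 3. With these sets as a block on the 6 arrays other than siRNA replicate 2, a fit added after the data were examined, 21 genes passed, 16 higher and 5 lower. Of these, 15 belonged to the interferon list. The sets were drawn from the same values that were tested, so the adjusted p-values of this fit may be too small. The 5 lower genes, named after their values were seen, were SYTL2 at -1.53, SKP2 at -1.38, TMEM218 at -1.25, LXN at -1.11 and SLC25A45 at -1.06.

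Genes of mitosis and the G2/M phase, which build the spindle and drive cell division, were lower in siRNA samples, with negative differences for 48 of 48 tested members. The list mean was 6.88 ± 0.71 (SD, n = 4) against 8.0 ± 0.25 (SD, n = 3), a difference of -1.13 (exact permutation p = 0.0571, or 0.625 adjusted over the 35 lists). KIF20A, a kinesin of cytokinesis, differed by -2.22 (SE 0.33, limma adjusted p = 0.468) and was the 1 member past the threshold adjusted over the list alone, against 0 over all genes. CDC20, an activator of the anaphase-promoting complex, differed by -1.69, CDKN3 by -1.31 and the cyclin CCNB2 by -1.10, each below every untreated sample in 4 of 4 siRNA samples. The list fell relative to other genes with camera (adjusted p = 1.34e-19), and adjusted p = 0.575 with an estimated correlation. Without siRNA replicate 2 the difference was -0.82, and 32 members were lower adjusted over the list alone. The list of DNA replication and S phase differed by -0.27 over 43 members (camera adjusted p = 0.632), by -0.045 without siRNA replicate 2, and by -0.52 and 0.35 within the sample sets of siRNA replicate 1 and of siRNA replicates 3 and 4. It passed in 2 of 18 alternatives, at 0.00518 with no filter and 0.048 without siRNA replicate 4, with adjusted p-values up to 0.988 in the others. TK1, the S-phase thymidine kinase, differed by -0.88 (limma adjusted p = 0.751).

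**Figure D2:**
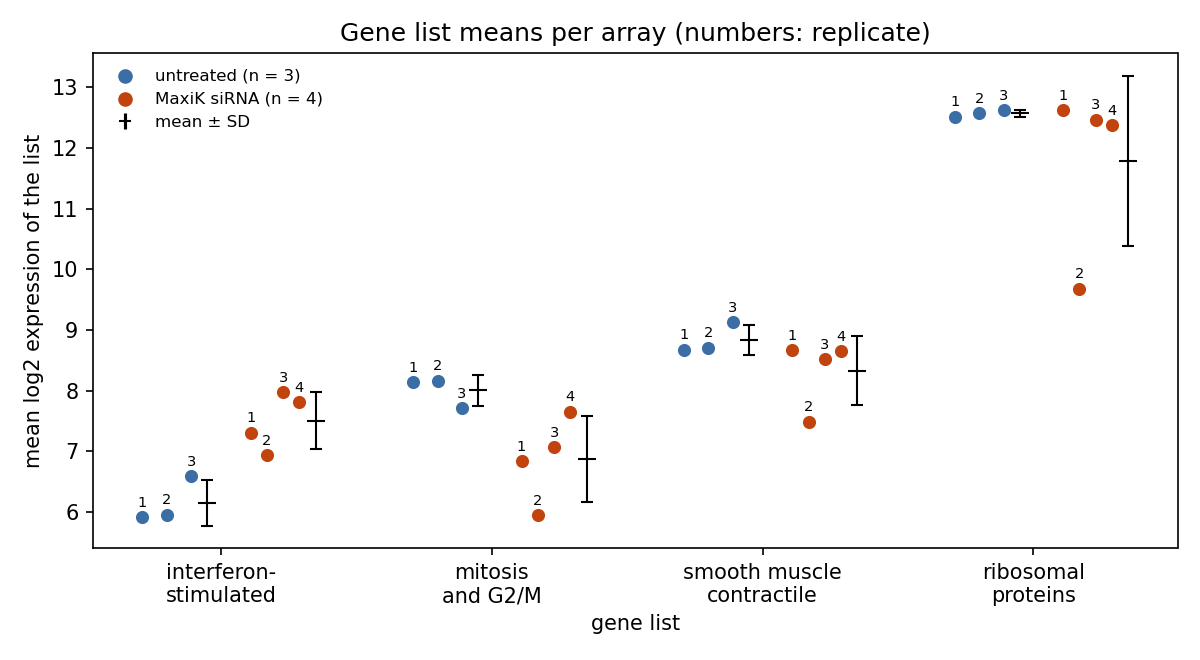
Mean log2 expression of 4 gene lists on each array, untreated (blue, n = 3) and MaxiK siRNA (red, n = 4), with replicate numbers and the mean ± SD in black. Interferon-stimulated genes sit at 6.94 to 7.98 in siRNA and 5.91 to 6.59 in untreated samples, and ribosomal protein genes at 9.68 in siRNA replicate 2 against 12.38 to 12.62 on the other arrays.

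A further 6 lists passed with camera, and for each the estimated correlation ended the call. Cholesterol synthesis genes were higher by 0.10 (15 of 21 members positive, camera adjusted p = 0.00663, adjusted p = 0.575 with an estimated correlation), or 0.25 without siRNA replicate 2. The list missed the threshold in 3 of 18 alternatives: at -0.0029 without siRNA replicate 3 (adjusted p = 0.0717), at 0.065 without siRNA replicate 1 (adjusted p = 0.0558) and at 0.11 with no filter (adjusted p = 0.153). DHCR7, HMGCS1 and SREBF2 differed by 0.45, 0.40 and 0.39. Immediate early genes were higher by 0.20 (17 of 27 positive, camera adjusted p = 0.0154, adjusted p = 0.591 with an estimated correlation), with MAFF at 1.05, or 0.63 without siRNA replicate 2, and NR4A1 at 0.34. Without siRNA replicate 2 their mean difference was 0.33. The list missed the threshold in 5 of 18 alternatives: at 0.067 without siRNA replicate 4 (adjusted p = 0.142), where the replicate block gave an adjusted p of 0.10, at 0.12 without siRNA replicate 3 (adjusted p = 0.0707), at 0.13 without untreated replicate 3 (adjusted p = 0.311) and at 0.24 with no filter (adjusted p = 0.196). Adjusted over the list alone, 0 members of either list passed, as over all genes.

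The other 4 lists passed only with siRNA replicate 2 in the fit. Ribosomal protein genes differed by -0.78 (38 of 39 negative, camera adjusted p = 0.00388, adjusted p = 0.909 with an estimated correlation) and by -0.080 without that sample (adjusted p = 0.154), and missed the threshold in 3 of 18 alternatives, also with array weights (adjusted p = 0.406) and with the sample-set block on 6 arrays (adjusted p = 0.438). RPL12 and RPS29 differed by -0.42 and -0.51, and by -0.15 and -0.16 without it. Oxidative phosphorylation genes differed by -0.59 (40 of 44 negative, camera adjusted p = 0.0154, adjusted p = 0.909 with an estimated correlation) and by -0.088 without it (adjusted p = 0.233), and missed the threshold in 4 of 18 alternatives, also with the filter at the 60th percentile (adjusted p = 0.128), with array weights (adjusted p = 0.269) and with the sample-set block on 6 arrays (adjusted p = 0.873). COX5B, a subunit of cytochrome c oxidase, differed by -0.95 and NDUFB10, a subunit of complex I, by -0.43, and by -0.47 and -0.33 without it. Endothelial markers differed by 0.32 (9 of 10 positive, camera adjusted p = 0.00115, adjusted p = 0.575 with an estimated correlation) and by 0.19 without it (adjusted p = 0.0562), and missed the threshold in 3 of 17 alternatives, also with array weights (adjusted p = 0.0552) and with the sample-set block on 6 arrays (adjusted p = 0.0875). Of its members, NOS3 was at 0.43, FLT1 at 0.41 (0.22 without it) and EGFL7 at 0.35. Leukocyte markers had 3 tested members and differed by 0.35 (camera adjusted p = 0.031, adjusted p = 0.575 with an estimated correlation) and by 0.21 without it (adjusted p = 0.275), and missed the threshold in 7 of 17 alternatives, also without siRNA replicate 1 (adjusted p = 0.083) or untreated replicate 3 (adjusted p = 0.144), with quantile normalization (adjusted p = 0.0779), with the mean of probe sets (adjusted p = 0.144), with array weights (adjusted p = 0.604) and with the sample-set block on 6 arrays (adjusted p = 0.30). TYROBP differed by 0.62, ITGB2 by 0.48 and SRGN by -0.036, and SRGN turned to 0.19 after quantile normalization. Adjusted over the list alone, 0 members of these 4 lists passed, as over all genes.

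**Figure D3:**
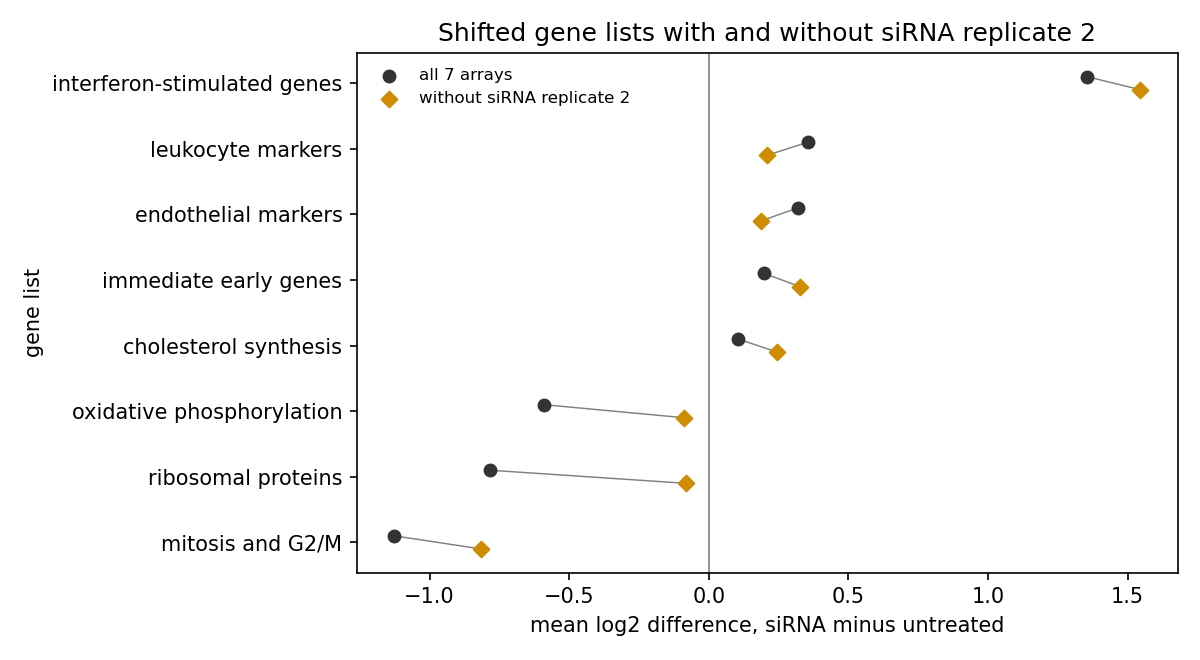
Mean log2 difference, siRNA minus untreated, of the 8 gene lists that passed with camera, from all 7 arrays (circles) and from 6 arrays without siRNA replicate 2 (diamonds). The interferon list moves from 1.35 to 1.55 and the mitosis list from -1.13 to -0.82, while the ribosomal list moves from -0.78 to -0.080.

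Smooth muscle contractile genes differed by -0.51 over 30 members, 25 of them negative, and did not pass (camera adjusted p = 0.0802, adjusted p = 0.872 with an estimated correlation). With the replicate block the adjusted p was 0.0391, and 0.798 with an estimated correlation as well. The list passed in 9 of 18 alternatives with the preset correlation, at adjusted p-values from 0.000933 to 0.495. LMOD1, a leiomodin that nucleates actin, differed by -0.94 (SE 0.28), MYOCD, the myocardin coactivator, by -1.07 (SE 0.50), SYNM by -1.09 and SYNPO2 by -1.04, each at a limma adjusted p of 0.751. MYOCD read 5.675, 5.773 and 7.383 in untreated replicates 1, 2 and 3, so the size of its difference depends on the last. Extracellular matrix genes differed by -0.33 over 45 members (camera adjusted p = 0.145, adjusted p = 0.931 with an estimated correlation). With the replicate block the adjusted p was 0.0205, and 0.798 with an estimated correlation as well, and the list passed in 6 of 18 alternatives with the preset correlation, at 0.000597 to 0.98. COL8A1, a collagen chain, differed by -1.24 and LOX, a collagen cross-linking oxidase, by -0.74. Without siRNA replicate 2 the contractile list differed by -0.23 and the matrix list by -0.00047, with SYNM at -0.71, SYNPO2 at -0.61 and LOX at -0.41.

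Genes of ion transport and vascular tone showed no list past the threshold with all arrays. The mean differences of the potassium, calcium, nitric oxide and vasoactive lists were negative, beside a median of -0.159 over all tested genes. Relative to other genes, camera gave the direction of each of these lists as up, and the adjusted p-values belong to that direction. Other potassium channels differed by -0.038 over 17 members (camera adjusted p = 0.150), calcium entry channels by -0.11 over 19 (adjusted p = 0.877), and calcium stores, pumps and buffers by -0.16 over 42 (adjusted p = 0.556). These lists differed by 0.032, -0.054 and 0.019 without siRNA replicate 2, so the sign turned for the first and the last, and other potassium channels passed in 1 of 18 alternatives, with no filter (0.15, adjusted p = 0.0308). The inward rectifiers KCNJ15, KCNJ5 and KCNJ8 differed by 1.35, 0.55 and -1.71, and without siRNA replicate 2 by 0.94, 0.36 and -0.85. CACNA1H, a T-type calcium channel, differed by 0.56, TRPC4 by -0.47, the mitochondrial uniporter MCU by -0.64 and the inositol trisphosphate receptor ITPR3 by 0.65. Nitric oxide and cyclic nucleotide genes differed by -0.19 over 33 members (adjusted p = 0.898), with GUCY1B1, a subunit of the nitric oxide receptor, at -0.78, PRKAR2B at -1.34 and PDE7B at -1.41. Vasoactive receptors and ligands differed by -0.11 over 32 members (adjusted p = 0.154), or -0.018 without siRNA replicate 2, with the muscarinic receptor CHRM2 at -1.35, S1PR3 at -0.88 and PTGS2, the inducible cyclooxygenase, at 1.06. Inflammatory NF-kB genes differed by 0.12 over 32 members (adjusted p = 0.165, past in 2 of 18 alternatives, at 0.0255 to 0.796), or 0.37 without siRNA replicate 2, with CXCL12 at -1.41, PTGES at -0.90, IRAK2 at 1.09 and CSF3 at 0.86. With all arrays none of the genes named here passed over all genes, and adjusted over the list alone the count was 0 in each of these lists. Values of siRNA and untreated samples overlapped for KCNJ8, ITPR3, PRKAR2B, PDE7B, CHRM2 and PTGS2, and lay apart for the other genes named here. With the sample-set block on 6 arrays, 2 vasoactive members were higher and 3 lower adjusted over the list alone. Of NF-kB members, 6 were then higher and 4 lower. Markers of other cell types did not pass either: fibroblast markers differed by -0.45 (adjusted p = 0.342), pericyte markers by -0.62 (adjusted p = 0.294), Schwann cell markers by -0.82 (adjusted p = 0.57) and epithelial markers by -0.27 (adjusted p = 0.881). These markers differed by -0.23, -0.21, -0.36 and -0.050 without siRNA replicate 2. Every other list tested missed the threshold with camera on all arrays, at adjusted p-values of 0.165 to 0.927.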

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

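The tests of siRNA replicate 2, of sample sets and of marker genes were chosen after the values they concern had been seen. The exception was the comparison of other cell types' markers in siRNA replicate 2 with random lists. The splits of the arrays for counts of genes and lists were set beforehand, and those for the shifts of lists afterwards.

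Among the 4 siRNA samples, 16 of 93 values had a sample far from the others (17.2%, where chance flags about 1 in 20 independent values), 14 of them siRNA replicate 2. The values come from the same 4 arrays and are not independent, so the share does not measure an excess over chance. That sample stood apart for KCNMB3 at 5.34, LOX at 9.03, TYROBP at 5.65, RPS29 at 10.37 and the GAPDH 3' control at 9.73. Its list means stood apart for calcium stores, pumps and buffers at 7.60, smooth muscle contractile genes at 7.49, extracellular matrix at 8.94, TGF-beta targets at 7.71, lysosome at 7.32, heat shock proteins at 8.17, ribosomal proteins at 9.68, Schwann cell markers at 6.10 and androgen and steroid response at 6.97. The siRNA replicate 1 sample stood apart for the mean of the hybridization spikes at 12.10 and for nitric oxide and cyclic nucleotide genes at 7.16. The hybridization spikes, control transcripts outside the main measurement, were higher by 0.488 on siRNA than on untreated arrays (exact permutation p = 0.0286, the smallest possible). That test too ignored the pairing by replicate number.

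A candidate explanation for siRNA replicate 2 is a lower quality or amount of its target RNA. Its deviation from the other siRNA samples fell with expression level across genes (Spearman rho -0.546), from a median of 0.451 in the dimmest of 5 equal groups of genes to -1.29 in the brightest. The 5' minus 3' values of the control genes were mixed. For GAPDH the value was -0.99 in siRNA replicate 2 and -0.57 to 0.12 on the other arrays. For ACTB it was -3.05, inside the -3.48 to -2.88 of the other arrays, so RNA quality was not settled. A failed hybridization is argued against by spikes that differed by 0.0892 from the other siRNA arrays, and a swap with an untreated sample by the lack of a partner, since KCNMA1 in every untreated sample was at least 1.37 above, and the interferon list at least 0.719 below, siRNA replicates 1, 3 and 4. For untreated cells under the label of siRNA replicate 2, its interferon list stood at percentile 100 of 10000 random lists matched on level. Those lists were drawn gene by gene, so they do not carry shifts that interferon genes share. The list mean also varied among untreated samples, at 5.91, 5.96 and 6.59, beside 6.94 in siRNA replicate 2. KCNMA1 gave no answer either, with bright probe sets at percentiles 33.1 and 7.31 of probe sets of the same level. This explanation therefore stays open. Cells of another type are argued against by endothelial, leukocyte, Schwann and epithelial markers, of which the highest stood at percentile 68.2 of 10000 such lists, and beyond these no biological explanation was tested.

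For the rise of the interferon list, siRNA replicate 2 as the cause is argued against by a difference of 1.55 without it. Within the sample sets the list differed by 1.30 and 1.38, so a shift between these sets alone would not give the rise. The widest gap between samples of 1 group in a set was 0.168. That gap is a weak yardstick, since the sets were drawn from the same data, which keeps such gaps small. Each set also holds 1 sample of a group, whose spread there was not measured. White blood cells as the source of these transcripts are argued against by 19 leukocyte markers with a median difference of 0.219, 16 of them under the filter level in untreated samples (PTPRC 0.32, LAPTM5 0.258, CD52 0.178 and LYZ 0.226 among these) with an upper quartile of 0.268, beside 14 interferon genes under that level with a lower quartile of 0.293 and a median of 1.54, while a share too small to lift dim markers stays open. Of the 35 splits, 1, the real one, gave so large a shift of this list, and 1 so large a shift of any list, but the real shift and the highest other, of siRNA replicates 1, 3 and 4 against the rest, both round to 1.35. The list was singled out after its shift was seen, and the 8 splits that part all 3 same-numbered pairs are too few for a share under 0.05. With 0 arrays of cells given a non-targeting siRNA or the reagent alone, a response to transfected RNA and an effect of losing the channel cannot be told apart.

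The fall of the mitosis list was -0.815 without siRNA replicate 2, which argues against that sample as the whole cause. With the sample sets as a block on 6 arrays it was -0.829 (SE 0.347), with 34 members lower adjusted over the list alone. Camera then gave an adjusted p of 6.57e-17, and 0.827 with an estimated correlation. The list call rests on the preset correlation, so the sets as the whole cause are not excluded. Within the sets the difference was -1.31 and -0.348, and the latter lies inside the widest gap of 0.586 between samples of 1 group in a set, so a fall in both sets and a fall in 1 set alone cannot be told apart. In 2 of the 35 splits the shift was as large as the real 1.13, the highest other being 1.30, so chance is not excluded. With 0 arrays of cells given a non-targeting siRNA or the reagent alone, transfection and loss of the channel cannot be told apart here either.

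Chance is not excluded for the counts: 3 of 35 splits gave as many genes as the real 1, and 3 as many of at least 2-fold, with 41 the highest other in both. That split set siRNA replicates 3 and 4 and untreated replicate 3 against the rest, along the sample sets. The sets were defined from the same data, so this is no separate evidence for them. As many as the real 8 lists came in 22 of 35 splits (highest other 13), and as many as the real 4810 genes under array weights in 2 (highest other 5107). Among the 8 splits that part all 3 same-numbered pairs, as many lists came in 6, and as many genes, with or without array weights, in 1, the real one.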

How the results depend on the processing

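The sample-set blocks, and the estimated correlations without siRNA replicate 2, with such a block and with the replicate block, were chosen after seeing the data. KCNMA1 stayed negative in every alternative run, from -2.69 to -2.11 with 1 array left out and at -1.40 as the mean of its probe sets, and passed only under array weights (-2.97, limma adjusted p = 0.000281). The gene count of 1 and the count of at least 2-fold became 0 and 0 with the filter at the 60th percentile, which removed HERC5, the 1 gene called, and 22 of 55 named genes in all, so these have no value there, 0 and 0 with the replicate block, 0 to 1 for both with 1 array left out, 4810 and 683 with array weights, 21 and 21 with the sample-set block on 6 arrays, and 3 and 3 with that on 7. Array weights gave siRNA replicate 2 a weight of 0.0282 and untreated replicate 2 one of 7.85. The 8 shifted lists became 13 with no filter, 5 with the filter at the 60th percentile, 4 to 10 with 1 array left out, and 0 with an estimated correlation, with fry, with an estimated correlation without siRNA replicate 2 and with one plus the sample-set or the replicate block. The replicate block takes siRNA replicate 4, which has no partner, out of the fit, so its differences were those without that sample, where 0 genes and 9 lists passed. The block also gave 9 lists, 8 of them shared: relative to all arrays, immediate early genes were lost and the matrix list gained in both fits, while the contractile list was gained with the block alone and DNA replication and S phase without siRNA replicate 4 alone. Besides these and HERC5 the block changed no call of a named gene over all genes or of a list. The interferon and mitosis lists passed in 18 of 18 settings with the preset correlation, at differences of 1.17 to 1.93 and -1.39 to -0.82. KCNMB3 ranged from -0.00095 (without siRNA replicate 2) to 0.30 with 1 array left out and was -0.049 with the sample-set block on 6 arrays. SRGN turned to 0.19 with quantile normalization, 0.11 with the replicate block, 0.023 with the sample-set block on 7 arrays, and to 0.0076 and 0.11 without siRNA replicates 3 and 4, in a range of -0.24 to 0.11 with 1 array left out. The unfolded protein response list turned to 0.32 under array weights (adjusted p = 0.0255), and cholesterol synthesis, past in 15 of 18 settings, had a mean of -0.0029 without siRNA replicate 3 and no longer passed there. The causes were not tested. Dim genes near background limit what the arrays can show of the channel's accessory subunits.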

Other observations

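The values without siRNA replicate 2 come from a planned fit and were picked after they had been seen. The sample sets were defined from the data, and the differences between them were not tested. Without siRNA replicate 2, inflammatory NF-kB genes differed by 0.37 over 32 members, and 3 were higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0596). PTGS2, the inducible cyclooxygenase, then differed by 1.43 (SE 0.28, limma adjusted p = 0.340) and IRAK2, a kinase of interleukin-1 signalling, by 1.24, while CXCL12, a chemokine, differed by -1.18 and PTGES, a prostaglandin E synthase, by -0.82. Of immediate early genes, 2 were then higher adjusted over the list alone. COL8A1 differed by -1.45.

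Several lists differed between the sample sets. In the set of siRNA replicate 1 with untreated replicates 1 and 2, immediate early genes differed by -0.13, contractile genes by -0.029, matrix proteases and inhibitors by -0.014 and DNA replication genes by -0.52. In the set of siRNA replicates 3 and 4 with untreated replicate 3, the same lists differed by 0.65, -0.54, 0.50 and 0.35. Each set holds 1 sample of a group, so no spread within that group was measured there.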
